A study of Mus musculus with 6 samples.

How the data were processed

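Gene expression was measured in mouse bone marrow cells on 6 Affymetrix oligonucleotide arrays, 3 from mice labelled ASXL1-MT-transplanted and 3 from control mice labelled mock-transplanted. The titles of both groups carry the same transplant prefix, and the labels do not say what the mock mice received. Per the labels, the cells were the fraction left after magnetic depletion with antibodies to CD3e (T cells), B220 (B cells) and TER-119 (red cell precursors), and the ASXL1-MT mice had a disease resembling myelodysplastic syndrome. The series text gives the depletion for both groups, while the source label states it for mock alone. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 samples of a group came from separate mice or pools, so p-values measure only the spread between these samples, which may be technical. The array version named in the series text does not go with the content stated there, and the 45037 probe sets of the table go with the stated content.

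Per the submitters' processing notes, signals were made with MAS5. The deposited values were log values, taken here as log2, with each probe set centred on its median over the 6 arrays. No label states the log base, the centring or a floor, and these were read from the values. Row medians were 0 to within 5e-07. In 429 probe sets 2 or more arrays held exactly equal values, and in 425 of these the equal values were the lowest of the row, as a floor on dim signals gives, so a higher value was read as a brighter signal. Medians of the array columns were 0.021, 0.050 and 0.048 for ASXL1-MT replicates 1 to 3 and -0.045, -0.028 and -0.053 for mock replicates 1 to 3. Because centring removed the absolute levels, no value shows how strongly a gene was expressed, and a fold change holds only if the base is 2. For dim signals a large fold can come from values close to background. The number of arrays limits the precision.

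Part of the brightness was recovered from rounding. Single-precision logs of 8 and above lie on steps with an exponent of 20 binary places, and 17205 probe sets (38.2%) had their 3 highest arrays on that step, which for base 2 means a signal of 256 or more. These probe sets are called bright below, whatever the level of their other arrays. The median SD within groups was 0.18 for bright probe sets, against 0.81 for the other probe sets. On simulated signals the rule recovered 99.7% of the probe sets at that level and also took 11.6% of dimmer ones. The simulated signals had no difference between groups, so these shares were not tested for probe sets with large changes. There the rule may miss a probe set at that level, since a median between the groups can lie on a finer step.

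Gene symbols came from the platform annotation. It gave 1 symbol for 34945 probe sets, several for 932 and none here for 9160, and only the first kind was named. Of these, 34741 matched a gene of the RefSeq table of assembly GRCm38.p6 by gene ID. That table served for names alone, and no coordinates were used. A gene's value was the mean of its own probe sets, which gave 18193 genes.

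The comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 over all 6 arrays with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design fixed before the data were examined had an intensity trend in the variance model and took the brightest probe set of each gene. Both need the levels that centring removed, so the reported fit had no trend and genes were averaged. A trend was run among the alternatives below, on the centred values. The planned filter on the 40th percentile removed 0 probe sets. Settings with an offset, a floor or another filter on signal could not be run for the same reason. The planned check of RNA quality needs the Affymetrix control probe sets, of which the table used here held 0.

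Before the data were examined, 32 gene lists with 959 genes were written from textbook knowledge, of which 846 genes were measured. They stand in for the Gene Ontology sets named in the series text, which were not used here. The 30 lists with 5 or more measured genes, other than the sex-linked genes and the genes named with the study, were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists. Camera was repeated with an estimated correlation, and fry was run on the same lists. Some genes are in several lists.

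Named genes followed a rule fixed before the data were examined. It took the 15 probe sets with the largest change in each direction among those past the threshold, with 1 symbol and no overlap between the groups. From each list it took up to 4 members with the largest change among those past the threshold, or the 2 with the smallest p where none passed, and it took every measured sex-linked gene and gene named with the study. Alternatives were quantile normalization, cyclic loess, equal array medians, no filter, trend with robust settings, array weights, Welch's test as a count, a replicate block, and leaving out each array. Those added after seeing the data were the trend as first planned, bright probe sets alone, the probe set with the smallest spread per gene, and a covariate of handling stress. Camera has no robust setting, so only the trend was passed to it. In both trend settings the trend followed each row's mean after centring, which is not its intensity. Calls kept or lost under them do not show what the planned trend would give.

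The fit was tested on simulated data made from the arrays' own residuals for all 45037 probe sets. With 4000 probe sets changed, 0% of changes of 1 on the log2 scale were recovered, 50.6% of changes of 2 and 75.2% of changes of 4, with at most 2.2% false calls. With 200 changed, the shares were 0%, 0% and 52.5%. In the data 1642 of 2130 higher and 1200 of 1516 lower calls were 2-fold or more, so smaller changes were called too. Each simulated run held changes of 1 size, so its shares do not carry over to the calls reported here. A raised list was recovered, and it was the only list called. The residuals were shuffled for each probe set separately, which removes correlation between genes. The simulation therefore cannot show how often lists are called falsely in these data, where the estimated correlation was up to 0.614. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.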

Results

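Marrow cells depleted of T, B and red cell lineages were compared between 3 ASXL1-MT and 3 mock samples. ASXL1 is a chromatin regulator whose truncating mutations recur in myelodysplastic syndrome, and the comparison asks how expression differs between diseased and control marrow. All values are centred log2 values, and a change is the ASXL1-MT mean minus the mock mean.

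In ASXL1-MT marrow, 15 of 20 mature neutrophil genes were lower, with 13 of 19 genes of secondary and tertiary granules and 10 of 24 megakaryocyte genes. Higher were 15 of 20 genes of dendritic cells and MHC class II, 12 of 27 stem and progenitor genes and 3 of 9 Hoxa genes. Of these lists only mature neutrophil passed with an estimated correlation (adjusted p = 0.0486), with adjusted p = 0.251 for granule, megakaryocyte and dendritic genes, 0.265 for stem and 0.329 for Hoxa genes. Of 45037 probe sets, 2130 were higher and 1516 lower in limma's test, 8.1% in all, with a median absolute change of 1.40 on the log2 scale. At an unadjusted p under 0.05 the counts were 7230 and 4602. Of the calls, 2378 were bright probe sets, and bright probe sets fitted alone gave 6778 calls. The groups did not overlap in 15882 probe sets (35.3%), where chance gives 10%. The median change of all probe sets was 0.106, and it was 0.024 with array medians set equal. The higher calls were 58.4% of all calls as deposited, 49.9% with equal medians, 47.9% after quantile normalization and 46.2% after cyclic loess. The count fell with every array left out, to 1142 without ASXL1-MT replicate 1, 112 without replicate 2 and 66 without replicate 3, and to 674, 159 and 332 without mock replicates 1, 2 and 3. Of 18193 genes, 1207 were higher and 865 lower, and counts within lists are to be read against these shares. Below, a list's median change is followed by its value relative to the median of all genes, which was 0.11.

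Of 20 measured genes of mature neutrophils, 15 were lower and 0 higher, and 17 were lower when adjusted over the list alone. At an unadjusted p under 0.05, 17 were lower and 0 higher. Il1r2, a decoy receptor for interleukin 1, was lower by 18.0-fold (log2 change -4.17, SE 0.18, adjusted p = 0.00479 by limma). Trem1, which amplifies inflammatory signalling in myeloid cells, was lower by 19.7-fold, and the stefins Stfa2l1 and Stfa3, which inhibit cysteine proteases, were lower by 13-fold and 9.16-fold. Trem1's log2 change of -4.30 became -5.03 without ASXL1-MT replicate 1, and it passed in 1 of 6 fits with an array left out. The list's median was -1.37, or -1.48 relative to all genes, and its values were -0.77, -0.55 and -0.69 in ASXL1-MT against 0.72, 0.57 and 0.75 in mock. Camera gave an adjusted p = 3.98e-13. It was the only list past the threshold with an estimated correlation, where its adjusted p = 0.0486.

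Granule genes were also lower. Among 19 genes of secondary and tertiary granules, 13 fell and 0 rose, and 14 fell when adjusted over the list alone. Orm1, an acute phase glycoprotein, was lower by 6.16-fold, the granule protein Olfm4 by 5.78-fold, the membrane protease Adam8 by 5.66-fold and the gelatinase Mmp9 by 3.65-fold. The list's median was -1.08, or -1.19 relative to all genes, with an adjusted p = 5.39e-12 by camera and an adjusted p = 0.251 with an estimated correlation. Of 9 primary granule genes, 2 fell and 0 rose, and 4 fell when adjusted over the list alone. These were Elane, neutrophil elastase, at 2.08-fold and Nkg7 at 2.27-fold. That list had a median of -0.39, or -0.50 relative to all genes, an adjusted p = 0.00136, and an adjusted p = 0.376 with an estimated correlation. Some other members of these lists, chosen after their values were seen, did not pass. The log2 change was -0.18 for S100a8 and 0.00 for S100a9 in the mature neutrophil list, -0.17 for Camp and -0.45 for Ltf in the secondary and tertiary granule list and -0.18 for Mpo in the primary granule list.

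Megakaryocyte genes fell in 10 of 24 cases and rose in 0, and 13 fell when adjusted over the list alone. Thbs1, an adhesive protein of platelet granules, was lower by 19.6-fold, Rab27b, which acts in granule release, by 10.9-fold, the platelet chemokine Pf4 by 5.44-fold and the platelet receptor Clec1b by 3.65-fold. With an array left out the log2 change ran from -5.16 to -3.66 for Thbs1, which passed in 1 of 6 fits, and from -3.90 to -2.80 for Rab27b, which passed in 0. With the probe set of smallest spread Rab27b had a log2 change of -0.76 (adjusted p = 0.0684), and Thbs1 lost its call with the trend as first planned (adjusted p = 0.0576). The list's median was -1.41, or -1.52 relative to all genes, with an adjusted p = 2.02e-08 by camera and an adjusted p = 0.251 with an estimated correlation. Of 9 eosinophil genes 1 fell, Siglecf at 2.75-fold, and 0 rose, with 2 lower when adjusted over the list alone. The eosinophil median was -1.46, or -1.57 relative to all genes, at an adjusted p = 0.00214, and at an adjusted p = 0.394 with an estimated correlation. Fry gave the list an adjusted p = 0.105. Mock replicate 1 stood apart there at -0.24, against 1.54 and 1.59 in mock replicates 2 and 3, and the list's median ran from -2.38 to -1.04 with an array left out. Of 17 basophil and mast cell genes, 3 fell and 0 rose, and 6 fell when adjusted over the list alone. Hdc, which makes histamine, was lower by 5.23-fold and Csf2rb by 2.14-fold, and Fcer1a, a chain of the high affinity IgE receptor, had a log2 change of -7.17. Fcer1a was not called bright, and the size of its fall is uncertain. Its log2 change ran from -7.72 to -6.09 with an array left out, and it passed in 2 of those 6 fits. This list had a median of -0.31, or -0.42 relative to all genes, an adjusted p = 0.0133, and an adjusted p = 0.251 with an estimated correlation. On bright probe sets alone its median was 0.03 and its call was lost, with an adjusted p = 0.205.

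Genes of dendritic cells and MHC class II rose in 15 of 20 cases and fell in 0, and 16 rose when adjusted over the list alone. Siglech, a receptor of plasmacytoid dendritic cells, was higher by 11.9-fold, and Flt3, a growth factor receptor of progenitors and dendritic cells, by 11.3-fold. Ly6d, a surface marker of early lymphoid cells, was higher by 8.0-fold and Ciita, the master activator of MHC class II genes, by 6.95-fold. Siglech's log2 change was 2.77 without mock replicate 1 and 4.25 without mock replicate 2, and it passed in 1 of 6 fits with an array left out. The list's median was 2.11, or 2.0 relative to all genes, with values of 1.07, 0.78 and 0.95 in ASXL1-MT and -1.20, -0.77 and -1.06 in mock. Camera gave an adjusted p = 5.08e-09, and an adjusted p = 0.251 with an estimated correlation. Of 27 monocyte and macrophage genes, 1 rose and 2 fell, and the list did not pass (adjusted p = 0.777). Adjusted over the list alone, 4 rose and 4 fell. Vcam1 was lower by 20.1-fold, the iron exporter Slc40a1 was lower by 2.74-fold, and the scavenger receptor Cd163 was higher by 2.98-fold, which lost its call with trend and robust settings (adjusted p = 0.0695). This list's median of 0.24 and mean of -0.06 differ in sign.

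Stem and progenitor genes rose in 12 of 27 cases and fell in 1, with 14 higher and 3 lower when adjusted over the list alone. Besides Flt3, Hoxa9 was higher by 11-fold, Mecom, a transcription factor of stem cells, by 6.19-fold and Egfl7 by 5.56-fold. Meis1, a partner of HOXA9, was lower by 3.86-fold, named because it was the only member that fell. The probe sets of Mecom disagreed. The changes were 6.35 for 1438325_at and 2.18 for 1423011_at, and the change was -0.64 for 1422295_at, which did not pass. The list's median was 0.97, or 0.86 relative to all genes, with an adjusted p = 0.000945 by camera and an adjusted p = 0.265 with an estimated correlation.

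In the Hoxa cluster, which patterns the body axis and is active in blood stem cells, 3 of 9 genes rose and 0 fell, and 6 rose when adjusted over the list alone. These were Hoxa9, Hoxa7 at 8.54-fold and Hoxa5 at 5.44-fold. With an array left out Hoxa7's log2 change ran from 2.52 to 3.66, and it passed in 1 of 6 fits. Neither probe set of Hoxa5 passed alone, with adjusted p = 0.0591 for 1448926_at and adjusted p = 0.0585 for 1443803_x_at. The median was 1.54, or 1.43 relative to all genes, with an adjusted p = 0.0113 and an adjusted p = 0.329 with an estimated correlation. The call was lost with the probe set of smallest spread per gene (adjusted p = 0.117) and on bright probe sets alone (adjusted p = 0.277). Of 24 Hox genes outside that cluster, 2 fell and 0 rose, and 2 fell when adjusted over the list alone. Hoxc4 was lower by 8.80-fold and Hoxd11 by 6.78-fold. The median was -0.28, or -0.39 relative to all genes, with an adjusted p = 0.0232, and an adjusted p = 0.291 with an estimated correlation. The call was lost without mock replicate 3, where the median was -0.01 (adjusted p = 0.109), after cyclic loess (adjusted p = 0.0544) and by fry (adjusted p = 0.0789).

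Genes tied to the study by name were chosen from what is known of it, so their count is not independent evidence. Of these 5 genes, 2 rose and 1 fell, with 3 higher and 1 lower when adjusted over the list alone. Hoxa9 was 1.51, 1.5 and 1.75 in ASXL1-MT and -1.60, -1.45 and -2.58 in mock. Hoxa5 was 1.01, 0.76 and 0.80 against -2.22, -1.18 and -1.37. Hoxa10 had a log2 change of 2.21 and an adjusted p = 0.0692, and its probe sets disagreed, with 5.08 for 1431475_a_at and -0.66 for 1446408_at. The former was 5.76 without mock replicate 2 and 4.18 without mock replicate 3. On bright probe sets alone, where only 1431475_a_at counts, Hoxa10 passed (adjusted p = 0.00536). Hoxa10 was 0.47, 0.57 and 1.43 against -0.78, -0.83 and -2.55. Clec5a, a myeloid activating receptor, was lower by 2.03-fold (adjusted p = 0.0409), with -0.63, -0.24 and -0.44 against 0.76, 0.24 and 0.75. Its only probe set, 1421366_at, did not pass among probe sets (adjusted p = 0.0541), and the gene passed in 0 of 6 fits with an array left out. That probe set did pass after quantile normalization (adjusted p = 0.0447), after loess (adjusted p = 0.0457) and with equal array medians (adjusted p = 0.0475). The same held with both trend settings and on bright probe sets alone (adjusted p = 0.00941). Asxl1 itself had a log2 change of -0.10 (SE 0.12, adjusted p = 0.662), with -0.15, -0.03 and -0.04 against -0.02, 0.05 and 0.05. The gene passed as lower in limma's test on bright probe sets alone, at -0.54 (adjusted p = 0.00965). With the probe set of smallest spread Asxl1 also passed, at -1.19 (adjusted p = 0.0108). Its probe sets moved apart, with -1.19 for 1435077_at (adjusted p = 0.0297), 0.11 for 1434561_at and 0.79 for 1458380_at. The call of 1435077_at was lost in all 6 fits with an array left out (adjusted p from 0.0556 to 0.115). The labels do not say whether any of them detects the introduced sequence, so they do not check the labels.

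**Figure D1:**
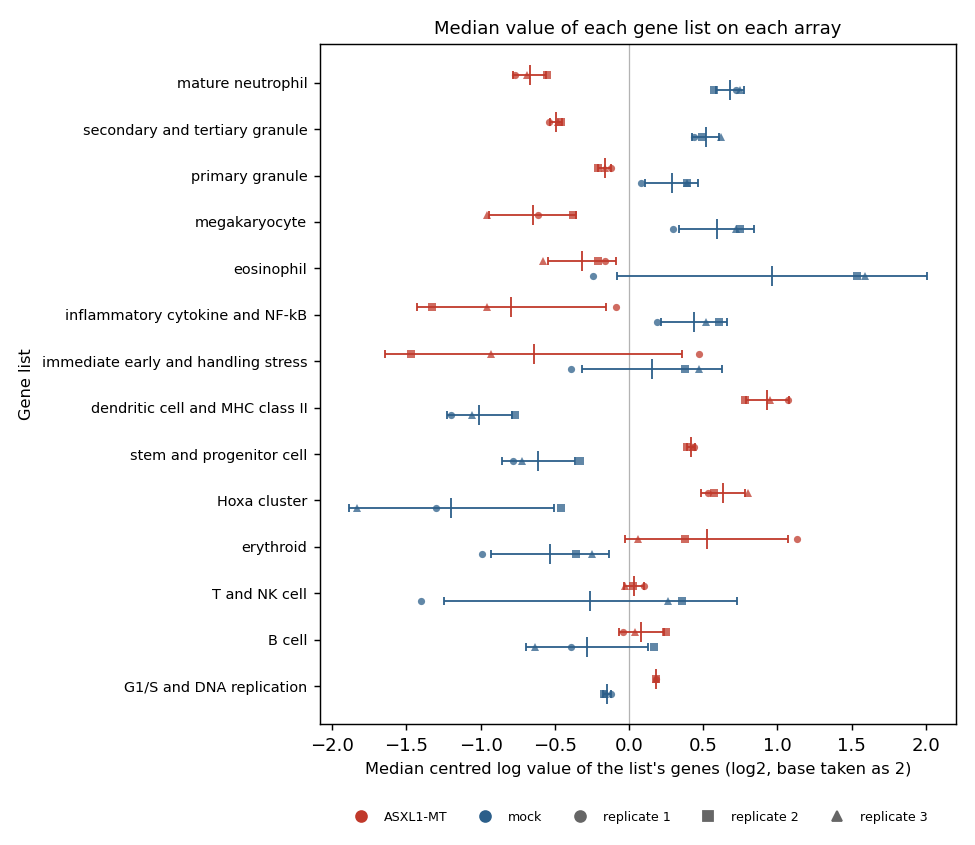
Median centred log2 value of each gene list (horizontal axis) for 14 lists (vertical axis). Points are the 6 arrays by group and replicate, vertical ticks the group means and bars 1 SD (n = 3 per group). The mature neutrophil medians lie between -0.77 and -0.55 in ASXL1-MT and between 0.57 and 0.75 in mock.

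ASXL1 binds Polycomb complexes, which silence developmental genes. Of 50 developmental Polycomb targets, 1 rose and 0 fell, and 1 rose when adjusted over the list alone. It was Cdkn1c, a cell cycle inhibitor, higher by 10.7-fold (SE 0.22 on the log2 scale, adjusted p = 0.00669). At an unadjusted p under 0.05, 4 were higher and 2 lower. The list did not pass (adjusted p = 0.447), and its median of -0.14 and mean of 0.08 differ in sign. Of 36 genes of Polycomb and ASXL complexes, 3 rose and 0 fell, and 3 rose when adjusted over the list alone. Pcgf6 was higher by 3.86-fold, Cbx6 by 3.67-fold and Bmi1 by 2.25-fold, and the list did not pass by camera (adjusted p = 0.121). It passed by fry (adjusted p = 0.00355), which tests whether the genes move one way and does not set them against other genes. Among 35 myeloid transcription factors, 3 rose and 5 fell, and the list did not pass (adjusted p = 0.128) except without ASXL1-MT replicate 1 (adjusted p = 0.0259). Adjusted over the list alone, 4 rose and 7 fell. Mxd1, which opposes MYC, was lower by 6.61-fold, Max by 2.54-fold, and Myc and Irf8 were higher by 5.38-fold and 3.18-fold.

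Lineages targeted by the depletion were examined as lists too. Erythroid genes rose in 3 of 30 cases and fell in 1, with 4 higher and 1 lower when adjusted over the list alone. Alas2, the first enzyme of heme synthesis in red cells, was higher by 15.8-fold, Tspan33 by 4.38-fold and Add2 by 3.43-fold, and Nfe2 was lower by 1.68-fold. Alas2 had a log2 change of 3.15 without ASXL1-MT replicate 1 and passed in 0 of 6 fits with an array left out. Tspan33 (adjusted p = 0.0616) and Add2 (adjusted p = 0.0638) lost the call with the probe set of smallest spread, and Add2 also with trend and robust settings (adjusted p = 0.0919). The median was 0.85, or 0.74 relative to all genes, with an adjusted p = 0.00429, and an adjusted p = 0.513 with an estimated correlation. On bright probe sets alone the adjusted p = 0.593, and by fry the adjusted p = 0.105. ASXL1-MT replicate 1 was the highest array at 1.13, with 0.38 and 0.06 in replicates 2 and 3. Of 28 B cell genes, 6 rose and 0 fell, and of 30 T and NK cell genes, 4 rose and 1 fell. Adjusted over each list alone, 7 rose and 1 fell among B cell genes and 4 rose and 2 fell among T and NK cell genes. Besides Ly6d, Fcrla, Cd22 and Bach2 were higher by 3.45-fold, 3.44-fold and 2.86-fold, and Cd22 lost its call with trend and robust settings (adjusted p = 0.103) and with the probe set of smallest spread (adjusted p = 0.0661). Cd8b1 and Cd8a, chains of the T cell coreceptor CD8, were higher by 12.8-fold and 7.96-fold, Klrd1 by 7.19-fold and Klrk1 by 2.84-fold. Without mock replicate 1 Klrd1's log2 change was 2.23, and it passed in 1 of 6 fits with an array left out. Neither list passed, with adjusted p = 0.50 for B cells and adjusted p = 0.491 for T and NK cells. Mock replicate 1 stood apart in T and NK cell genes at -1.40, against 0.36 and 0.26 in replicates 2 and 3. Of 27 stroma and endothelium genes, 3 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone. Bgn, Cxcl12 and Col3a1 were higher by 6.14-fold, 5.04-fold and 3.20-fold, and Pdgfrb was lower by 2.07-fold. With the probe set of smallest spread, Col3a1 turned to a log2 change of -0.57 (adjusted p = 0.447), and Pdgfrb lost its call (adjusted p = 0.132). That list did not pass (adjusted p = 0.104), but it passed without ASXL1-MT replicate 1 (adjusted p = 0.0428), without mock replicate 2 (adjusted p = 0.0479) and without mock replicate 3 (adjusted p = 0.0429).

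Of 37 genes of G1/S and DNA replication, 8 rose and 0 fell, and 9 rose and 1 fell when adjusted over the list alone. The cyclins Ccnd1 and Ccnd2 were higher by 9.09-fold and 2.42-fold, and the repair enzymes Ung and Fen1 by 1.94-fold and 1.83-fold. The median was 0.33, or 0.22 relative to all genes, with an adjusted p = 0.00136 and an adjusted p = 0.251 with an estimated correlation. Of 37 mitotic genes, 2 rose and 0 fell, while 0 passed when adjusted over the list alone and 18 were higher at an unadjusted p under 0.05. Anln was higher by 2.02-fold and Aurkb by 1.52-fold, and Aurkb lost its call with equal array medians (adjusted p = 0.0671). That median was 0.35, or 0.24 relative to all genes, with an adjusted p = 0.000111 and an adjusted p = 0.273 with an estimated correlation. Ribosome biogenesis genes rose in 4 of 36 cases and fell in 0, with 5 higher when adjusted over the list alone. These were Ebna1bp2 at 2.20-fold, Utp20 at 1.99-fold, Nop16 at 1.93-fold and Tcof1 at 1.88-fold. Utp20 lost its call with equal array medians (adjusted p = 0.0521) and after loess (adjusted p = 0.0611), and Nop16 after loess (adjusted p = 0.0593). Ebna1bp2 lost it on bright probe sets (adjusted p = 0.15) and with the probe set of smallest spread, where its log2 change was 0.14. The median was 0.49, or 0.38 relative to all genes, with an adjusted p = 1.61e-06 and an adjusted p = 0.376 with an estimated correlation.

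Metabolic lists moved in both directions. Of 20 cholesterol synthesis genes, 7 rose and 0 fell, and 8 rose when adjusted over the list alone. Cyp51 was higher by 3.59-fold and Sqle by 3.00-fold, and Lss and Tm7sf2 by 2.20-fold and 2.16-fold. Lss (adjusted p = 0.0621) and Tm7sf2 (adjusted p = 0.058) lost the call with equal array medians, as they did after quantile normalization and loess, and Cyp51 lost it with the probe set of smallest spread (adjusted p = 0.0527). The median was 0.39, or 0.28 relative to all genes, with an adjusted p = 0.00441, and an adjusted p = 0.474 with an estimated correlation. On bright probe sets alone the adjusted p = 0.0512. Of 18 glycolysis genes, 7 fell and 2 rose, with 8 lower and 3 higher when adjusted over the list alone. The glucose transporter Slc2a3 and the lactate transporter Slc16a3 were lower by 6.03-fold and 2.54-fold, and Aldoc and Pdk1 were higher by 3.79-fold and 3.73-fold. The median was -0.27, or -0.38 relative to all genes, with an adjusted p = 0.00456 and an adjusted p = 0.305 with an estimated correlation. Of 70 oxidative phosphorylation genes, 0 passed limma's threshold, and 4 were higher and 2 lower at an unadjusted p under 0.05. Atp5b had a log2 change of 0.44 and Ndufa3 of -0.46. With trend and robust settings Atp5b (adjusted p = 0.0356) and Ndufa3 (adjusted p = 0.0385) passed. Atp5b also passed on bright probe sets alone (adjusted p = 0.00853) and with the probe set of smallest spread (adjusted p = 0.0347). Among 42 ribosomal protein genes 1 passed, Rpl37 at 1.52-fold higher, which lost its call with equal array medians (adjusted p = 0.0669). Of 23 heme and iron genes, Alas2 rose and Slc40a1 fell. None of these 3 lists passed, with adjusted p = 0.777, 0.128 and 0.397. The ribosomal protein list passed without ASXL1-MT replicate 2 (adjusted p = 0.0483) and without mock replicate 3 (adjusted p = 0.0496).

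Inflammatory cytokine and NF-kB genes fell in 7 of 36 cases and rose in 0, with 9 lower when adjusted over the list alone. The neutrophil chemokine Cxcl2 was lower by 33.9-fold, the cytokine Il6 by 10.3-fold, Il1rn by 3.56-fold and Rel by 3.21-fold. With an array left out the log2 change of Cxcl2 ran from -5.94 to -4.14 and that of Il6 from -3.99 to -2.86. Cxcl2 passed in 0 of these 6 fits, and Il6 passed only without ASXL1-MT replicate 1. The median was -1.18, or -1.29 relative to all genes, with an adjusted p = 3.61e-07, and an adjusted p = 0.320 with an estimated correlation. Fry gave an adjusted p = 0.0530. The list's values were -0.09, -1.33 and -0.96 in ASXL1-MT and 0.19, 0.61 and 0.52 in mock, so ASXL1-MT replicate 1 stood apart. Immediate early and handling stress genes, which cells switch on within minutes of disturbance, were tested as a list of their own. Their mean was 0.65, -1.62 and -1.03 in ASXL1-MT replicates 1 to 3 and -0.42, 0.28 and 0.48 in mock. Of these 38 genes 1 rose, the chaperone Hspa8 at 1.92-fold, and 0 fell, while 0 passed when adjusted over the list alone and 6 were lower at an unadjusted p under 0.05. The list's median was -0.79, or -0.90 relative to all genes, with an adjusted p = 0.00303, and an adjusted p = 0.626 with an estimated correlation. Without ASXL1-MT replicate 2 the median was -0.26 and the adjusted p = 0.10, and by fry the adjusted p = 0.475. Of 40 interferon response genes, 5 rose and 0 fell, and 6 rose when adjusted over the list alone. Iigp1, Ifi203, Irgm1 and Mx1 were higher by 3.60-fold, 2.56-fold, 2.24-fold and 2.17-fold. Iigp1 lost its call with equal array medians (adjusted p = 0.0516), quantile normalization and loess, and Irgm1 with trend and robust settings (adjusted p = 0.0756). That list did not pass (adjusted p = 0.785), and its median of -0.01 and mean of 0.13 differ in sign. Of 34 apoptosis and p53 response genes, 7 fell and 4 rose, the same counts as when adjusted over the list alone. Gadd45a and Fas were lower by 6.58-fold and 2.50-fold, and the survival factor Bcl2 and Sesn1 were higher by 3.68-fold and 2.60-fold. The median was -0.14, or -0.25 relative to all genes, with an adjusted p = 0.0362, and an adjusted p = 0.265 with an estimated correlation. That call was lost without ASXL1-MT replicate 2 (adjusted p = 0.0554), without replicate 3 (adjusted p = 0.10) and without mock replicate 3 (adjusted p = 0.101). It was also lost on bright probe sets alone (adjusted p = 0.205), with the probe set of smallest spread per gene (adjusted p = 0.196) and by fry (adjusted p = 0.0719).

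**Figure D2:**
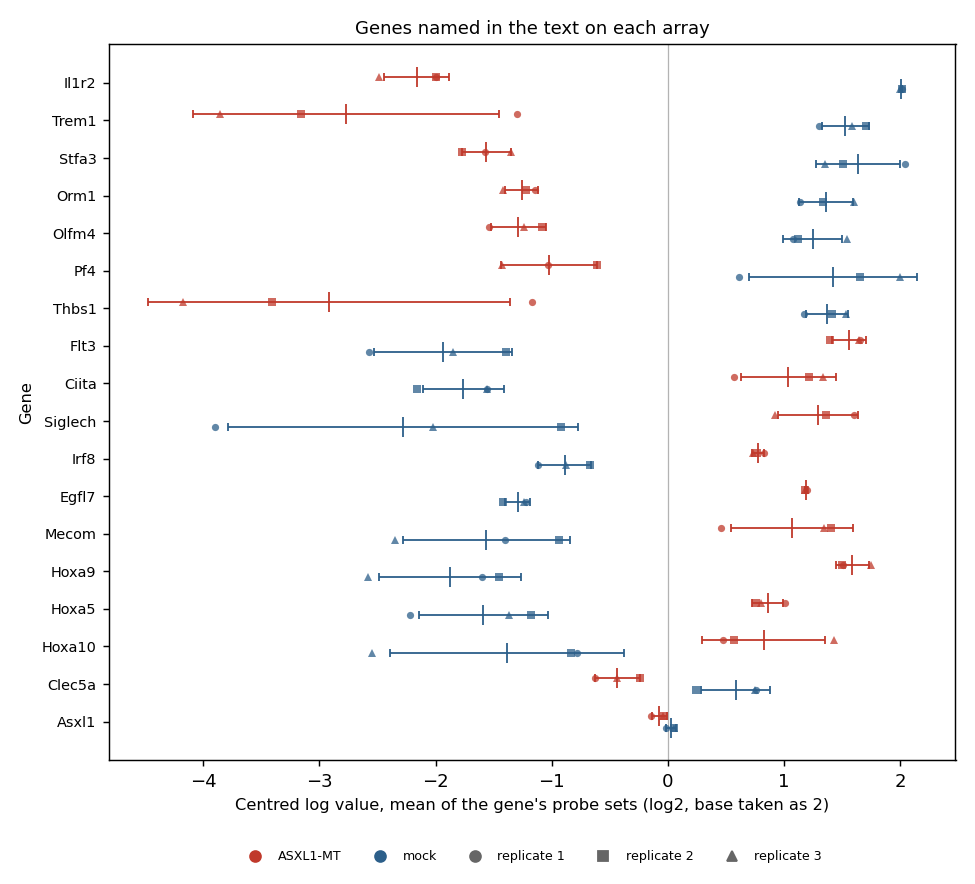
Centred log2 value of 18 named genes (vertical axis) on each array (horizontal axis), as the mean of each gene's probe sets. Points are the 6 arrays, vertical ticks the group means and bars 1 SD (n = 3 per group). Hoxa9 lies between 1.5 and 1.75 in ASXL1-MT and between -2.58 and -1.45 in mock, and Asxl1 lies near 0 in both.

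The largest single changes were in probe sets of mixed function. Among the 15 with the largest rise, the embryonic globin Hbb-y was higher by 501-fold, Bpifc by 176-fold and Mecom by 81.4-fold, and Mn1, a transcriptional regulator involved in leukemia, had a log2 change of 7.09. With an array left out the log2 changes ran from 8.56 to 9.70 for Hbb-y, from 5.87 to 8.36 for Bpifc and from 6.19 to 7.55 for Mn1, which passed in 4, 1 and 1 of 6 fits. The others were 1810073O08Rik, Ddx4, Upk1b, Tlr3, Plekha7, Tnfsf11, Fgf13, Pdcd1, Cdh17, A930009L07Rik and Fam20a. Of these, Ddx4 (adjusted p = 0.0518) and Tnfsf11 (adjusted p = 0.0516) lost the call with equal array medians, and Tlr3 lost it with the trend as first planned (adjusted p = 0.118). Among the 15 with the largest fall, Acod1, which makes itaconate in activated macrophages, was lower by 244-fold, and the log2 change was -7.83 for Tmem45a2, -7.17 for Fcer1a and -6.99 for Bmpr1a. Mn1, Tmem45a2, Fcer1a and Bmpr1a were not called bright, though the rule may miss bright probe sets at such changes. Their lower group can lie at background. Brightness was read from the 3 highest arrays alone, so this also holds for bright probe sets such as Hbb-y, Bpifc, Mecom and Acod1. Ugt8a was bright with 2 ASXL1-MT arrays at the floor. The size and rank of all these changes are uncertain. With an array left out the log2 change ran from -8.72 to -6.64 for Acod1 and from -8.60 to -7.16 for Tmem45a2, which each passed in 2 of 6 fits. The rest were Tslp, Ces1d, Ugt8a, Pla2g7, Hnmt, Prok2, Jag1, Fundc2, Gspt2, Vcam1 and Rnf217. Ugt8a lost its call with trend and robust settings (adjusted p = 0.0564) and with the trend as first planned (adjusted p = 0.522). Neither trend follows intensity on centred values. Of the 30 probe sets 15 were bright, 16 moved by more than 1.5 times with an array left out, and 7 kept their call whichever array was left out. The rule named 89 genes that passed, whether or not their list did. Of these 89 genes, 13 kept their call whichever array was left out, and all 89 kept their direction. These 13 were Orm1, Olfm4, Adam8, Il1r2, Stfa3, Vcam1, Ly6d, Egfl7, Cdkn1c, Pcgf6, Cd8b1, Cd8a and Ccnd1. The kept direction is no support, since the genes were picked on these same arrays. Where groups do not overlap, leaving out 1 array cannot turn a change. For genes with bright probe sets a large fold can likewise come from a lower group at background. Of the 89, 23 had no probe set called bright, and the size of their change is uncertain whatever the fold. Besides Fcer1a these were Cxcl2, Rab27b, Stfa3, Hoxc4, Hoxd11, Clec1b, Slc16a3, Ifi203, Col3a1, Add2, Cd22, Fcrla, Iigp1, Tspan33, Bgn, Ciita, Hoxa7, Cdkn1c, Hoxa9, Siglech, Cd8b1 and Alas2.

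Sex-linked genes were given on every array. Uty, a Y-linked histone demethylase, was higher in ASXL1-MT by 3.98-fold (adjusted p = 0.0312), with 0.69, 0.53 and 0.86 against -0.52, -1.64 and -1.74, and it passed in 1 of 6 fits with an array left out. Kdm5d had a log2 change of 1.03, with 0.31, 0.89 and 0.39 against 0.45, -0.90 and -1.04, and its probe set 1424903_at changed by 2.02 (adjusted p = 0.0130) and passed in 2 of those fits. Eif2s3y had a change of 0.46, with 0.55, 0.25 and -0.02 against 0.04, -0.29 and -0.38. Xist, the RNA that silences an X chromosome in female cells, had a change of -0.68 (SE 0.59), with 0.19, 0.09 and -0.60 against 1.80, 0.04 and -0.13. Of these 4 genes 1 passed, over all genes and when adjusted over the list alone. On bright probe sets alone Kdm5d also passed in limma's test, at 2.02 (adjusted p = 0.000759), as did Eif2s3y, at 0.80 (adjusted p = 0.00598). With the probe set of smallest spread both passed again (adjusted p = 0.00369 and adjusted p = 0.0204).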

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

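The alternatives called trend as first planned, bright probe sets and smallest spread per gene were chosen after seeing the data. The no-filter setting equals the reported fit and tests nothing, and the settings with an offset, a floor or another signal filter were not run because levels were removed. The counts of higher and lower probe sets were within 1.5 times under quantile normalization, loess, equal medians, weights and the trend as first planned. The trend settings do not follow intensity on centred values, so they do not test the planned trend. Higher calls were 3555 with trend and robust settings. Welch's test called 380 higher and 289 lower and the cause was not tested. Bright probe sets alone gave 4067 and 2711 among 17205 tested, 6778 in all, against 2378 bright calls in the reported fit. The number of calls thus depends on which probe sets are fitted together, and 8.1% does not give the extent of change. An adjusted p under 0.1 gave 4317 and 2852, and an unadjusted p under 0.05 gave 7230 and 4602. Leaving out 1 array gave 27 to 511 higher and 39 to 631 lower, with fewer samples. Same-numbered residuals correlated at -0.009, -0.012 and -0.009, which gave no sign that the replicate numbers pair the samples. The correlations ran over all probe sets, most of them not bright and with a wide spread, so they cannot exclude a pairing. With a replicate block limma called 0 probe sets higher and 0 lower, against 5826 and 4048 at an unadjusted p under 0.05. Of the 8 higher and 11 lower lists, 5 higher lists passed on bright probe sets, and 0 higher and 1 lower with an estimated correlation, against 2 and 3 at an unadjusted p under 0.05. Fry passed 6 lower lists. The cause was not tested.

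Of the 19 lists that passed, 16 kept the call and all 19 the direction whichever array was left out. Stroma also passed in 3 of these fits and with the replicate block (adjusted p = 0.048), transcription factors in 1, ribosomal protein in 2, and Polycomb and ASXL complex by fry (adjusted p = 0.00355). Apoptosis was lost with the block (adjusted p = 0.0513). Some lists that did not pass turned direction in camera, which can differ from the sign of the median. The oxidative phosphorylation median of 0.07 became -0.03, -0.04 and -0.01 under quantile, loess and equal medians, and stayed positive, at 0.02 to 0.11, with an array left out, where only camera's direction turned. The monocyte median also stayed positive, at 0.18 to 0.24 (0.13 on bright probe sets), while camera turned at adjusted p = 0.929 and 0.933. Median ranges were -0.29 to 0.71 for T and NK cells and -0.13 to 0.10 for interferon (0.03 on bright probe sets). Fry turned the Polycomb target list, of median -0.14. Probe sets that did not pass turned too, with ranges of -0.03 to 0.27 for Asxl1 probe set 1434561_at, -0.05 to 0.36 for Eif2s3y 1431642_at, -1.86 to 0.32 for Kdm5d 1452562_at, -1.82 to 0.42 for Mecom 1422295_at and -0.66 to 0.85 for Xist 1427262_at (0.23 with array weights). With the smallest-spread probe set, Col3a1, which had passed, turned from 1.68 to -0.57 and Hoxa10, which had not, to -0.66. On bright probe sets alone Hoxa10 went the other way and passed in limma's test, at 5.08 (adjusted p = 0.00536). The cause was not tested. Signal over background cannot be read from centred values, which limits all dim probe sets and the lower group of bright ones.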

Other observations

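The tests of other splits, of scaling, of cell shares and of Xist were chosen after the result was seen, and so was the immediate early covariate, although its bounds were set before its result was seen. The rule that quartiles as well as medians must pass a bound was set after the values were seen.

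The 10 splits of the 6 arrays into 3 and 3 cannot give a share under 0.05. For probe sets, 1 of the 10 splits, the real one, reached its 3646 calls, and the highest of the other 9 was 0 by limma, with 1519 to 2039 at an unadjusted p under 0.05 against 11832. For lists, 1 of the 10 splits reached the real 19, and the other 9 called 5 to 14 lists each. Camera at the preset correlation thus also passed lists where the groups were mixed. Its small p-values and the count of 19 lists are limited by this.

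Of 20 mature neutrophil genes, 15 were lower in ASXL1-MT. A difference in scaling between the arrays would bring the median near 0 once array medians are equal. The mature neutrophil median was then -1.45 (quartiles -2.79 and -0.91), against -1.37 as deposited. Array medians lay between -0.053 and 0.05, so this setting could move the list only slightly and its outcome was fixed beforehand. A shift of whole arrays of that size is too small for the fall. A lower share of neutrophils alone would raise markers of every other cell type, and the megakaryocyte median was -1.41 (quartiles -1.93 and -0.49), while that of dendritic cells was 2.11. Both lists lost their call with an estimated correlation (adjusted p = 0.251). With handling stress as a covariate the neutrophil median was -1.44 (quartiles -2.61 and -0.84). A change in the maturation of neutrophils or in several cell types at once, as the disease in the labels might bring, stays open as a hypothesis and was not tested.

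Of 36 inflammatory genes 7 were lower, and the list lost its call with an estimated correlation (adjusted p = 0.320) and by fry (adjusted p = 0.0530). Handling stress of the cells before lysis could contribute. With each array's immediate early mean as a covariate, the median over the 35 genes outside that list moved from -1.18 to -0.75, with an adjusted p = 8.67e-06 by camera at its preset correlation. The median and p meet the bound of -0.5 that was set for excluding handling as the whole cause, but the quartiles of -1.41 and 0.05 span it. By the rule on quartiles, which was set after the values were seen, handling and ASXL1-MT were left as not told apart for this list. Quartiles show how members differ and give no error for the list's change, so they do not decide it either way.

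Of 9 Y-linked probe sets, 4 were higher in ASXL1-MT, 3 of Uty and 1 of Kdm5d. With an array left out they kept the call in 1 or 2 of 6 fits. The median of the 5 bright ones was 1.66 with equal array medians (quartiles 1.35 and 1.94), against 1.74 as deposited. Array medians differed too little for this setting to move it far. A shift of whole arrays of the size seen is too small to account for it. Single probe sets differed, since Uty 1457582_at lost its call with equal medians (adjusted p = 0.0573), and Kdm5d 1452562_at changed by -0.80 and Eif2s3y 1431642_at by 0.13. Female cells among the mock samples would raise Xist there, and its change was -0.68 with a 95% interval from -2.31 to 0.96, so this cannot be told apart from no difference. None of its 3 probe sets was bright, so the interval rests on dim values. Xist was 1.80 in mock replicate 1, while mock replicates 2 and 3, at 0.04 and -0.13, lay within the ASXL1-MT range of -0.60 to 0.19. The sex of donors and recipients is not given in the sources used here, and no biological explanation was tested.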
